A study of Mus musculus with 7 samples.

How the data were processed

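Total liver RNA of 7 mice was hybridised to Affymetrix mouse U74Av2 arrays, which have 1 colour, and read with a Hewlett-Packard GeneArray scanner, per the labels. The deposited values are intensities on a linear scale, 1 per probe set and array. The software that made them, its version and its scaling target are not given in the sources used here. The values showed that they had been scaled: the mean after trimming 2% at each end lay between 500.36 and 500.39 on every array, while the medians ranged from 157 to 170.05. No deposited intensity was 0 or lower, and no detection calls were used here, so a signal near the floor cannot be told from background. The number of arrays, not a count of reads, limits the precision.

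The table held 12488 probe sets, of which 66 were Affymetrix controls. Platform annotation gave 10855 probe sets a single gene symbol, 396 several genes and 1237 none. Probe sets with several genes or none were left unnamed and unused. Gene identifiers matched 10839 of the 10855 to the RefSeq gene table of assembly GRCm38.p6, which changed no symbol. The arrays name no genome build, so no coordinates are given.

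Each array was scaled to the same trimmed mean, values below 0.1 of that mean (50.04) were set to it, and log2 was taken. A gene with several probe sets was represented by the one with the highest mean, which left 8251 genes. Genes with a mean of at least 0.4 of the trimmed mean (200.1) were tested, 4481 in all. Signals in the text are means ± SD of scaled values before the floor. Probe sets with the suffixes _f_at, _s_at, _g_at, _r_at and _i_at can read related genes or follow relaxed design rules.

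All 7 samples formed 1 group, so tests were made for spread and not for differences. An intercept-only model was fitted with limma 3.58.1 in R 4.3.3. Each gene's variance was set against a prior that follows the mean level and was estimated robustly (prior degrees of freedom 5.61), with an upper-tail F test and Benjamini-Hochberg adjustment at 0.05. The same step was tested on simulated data for 4481 genes with 200 changed: it recovered 0, 0 and 57 genes whose SD was raised 2, 3 and 5 times, with 2 false calls at 5 times.

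43 gene lists with 727 genes, 557 of them on the array, and 15 list pairs were fixed before the data were examined, as were the main tests and most alternatives. For lists with at least 5 tested genes, the median SD and the mean pairwise Pearson correlation across animals were ranked among 10000 random lists matched on level in 20 bins. In simulated data of otherwise independent genes, 3 of 100 unrelated lists of 12 genes and 100 of 100 lists sharing 1 factor reached the top 2.5%. The factor had a size of 1 expected SD and was drawn once for all 100 lists, so this share does not estimate power. A list score is the mean over tested genes of the log2 signal minus the gene's mean. Correlations of scores used Pearson's r and Spearman's rho with exact two-sided permutation tests over all 5040 pairings, adjusted over the 13 pairs that could be tested. Members with an unadjusted p under 0.05 were also counted after adjustment over the list alone. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for plots.

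Genes named in the text come from rules fixed beforehand: the 15 with the highest level, the 5 with the smallest log2 SD, in each list up to 4 of the highest level and up to 2 of the largest log2 SD, and Igf1, Igfals, Xist, Y-linked and Mup genes whatever their values. A further rule, for genes that passed the test of spread, named none, so the 25 genes with the largest SD over the expected SD were added after their values were seen. Ckm and Myh4 were also chosen after their values were seen.

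Array sets were read from the mean log2 signal of the bacterial spike-in controls, split at its widest gap. The fit with the set as a term, scores and genes with set means removed, results without replicates 1 and 2 together, and coherence with the trend with each 3' to 5' ratio removed were chosen after seeing the data, as was the count of lists in the top 2.5%. Alternatives fixed beforehand were no scaling, median centring, quantile normalization, floors of 0.05 and 0.2, an added offset in place of the floor, filters of 0.2 and 0.8 or none, the mean of all probe sets, leaving out each array, and priors without the robust step or the trend.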

Results

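Liver RNA of 7 female mice was measured, each on 1 array. The animals were phenotypically normal mice (genotype +/+ or +/df per the labels), fed without restriction and killed at 24 to 26 months of age. Their titles number them 1, 2, 3, 4, 6, 7 and 8, and these numbers name the replicates here. The labels disagree on genotype: the title, the source name and the series title name normal animals, while the description field names the dwarf genotype. The group was kept as the titles give it. All 7 samples formed 1 group, so no comparison between groups was made. The data give the level of each gene in this liver and the spread between animals, and the number of arrays limits the precision of both. Each label describes 1 mouse, but no label states outright that the 7 RNAs came from separate animals, so the spread includes any technical part.

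The brightest genes encoded secreted plasma proteins and metabolic enzymes of the hepatocyte. Albumin (Alb, NCBI gene 11657) had the highest signal, 31853 ± 3080 (SD, n = 7), followed by the apolipoprotein Apoe at 30635 ± 2883. The alpha-1-antitrypsin genes Serpina1b, Serpina1c and Serpina1e lay at 29331 ± 1981, 28355 ± 1442 and 28078 ± 2259, on probe sets that can read several members of that family. Plasminogen (Plg), Apoa1, fetuin (Ahsg), Apoc1 and Pzp followed, at means from 22977 for Pzp to 27043 for Plg. Among enzymes, Cyp2e1, a cytochrome P450 that oxidises ethanol, had 25440 ± 2768, and Cps1, which feeds ammonia into the urea cycle, had 22825 ± 1240. Mup3, a major urinary protein, the translation factor Eef1a1 and the desaturase Scd1 completed the 15 brightest genes, at 24288 ± 1700, 22080 ± 1718 and 22052 ± 3953. All 18 measured members of the plasma protein list were in the top 10% of the 8251 named genes. With quantile normalization the log2 SD of Alb was 0.03, against 0.14, and without replicate 3 it was 0.09. That of Apoe was 0.05 with quantile normalization, against 0.13. The log2 SDs of the other 12 of these genes apart from Scd1 were also smaller with quantile normalization, from 0.02 for Serpina1c, against 0.07, to 0.10 for Apoa1, against 0.17. Without replicate 3, those of Serpina1b and Pzp were 0.06, against 0.10 and 0.12, and that of Cps1 was 0.05, against 0.08. Quantile normalization by construction evens out the brightest genes, so the smaller SDs with it say little about the animals. Percentiles here rank signals of different probe sets and do not rank transcript amounts.

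The metabolic lists were bright as well. The urea cycle and amino acid list had a median signal of 8454 over 15 measured genes, with Arg1 at 14377 ± 826. The xenobiotic P450 list had a median of 5569 over 16 genes and included Cyp2d10 at 19626 ± 2215, Cyp3a11 at 14002 ± 1702 and Cyp1a2 at 13007 ± 2045. The fatty acid synthesis list had a median of 5514, and all 11 measured members were in the top 10%, among them Elovl5 at 12890 ± 807 and Thrsp, a regulator of lipogenesis, at 11458 ± 1691. The fatty acid oxidation list, with Acaa2 at 21478 ± 1328 and the fatty acid binding protein Fabp1 at 19166 ± 1913, had a median of 2046 over 27 genes. Fbp1 and Pck1, enzymes of gluconeogenesis, had 19213 ± 1658 and 4223 ± 724. The bile acid transporter Slc10a1 had 11654 ± 394, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 1396 ± 492. Hepcidin (Hamp) reached 20282 ± 1945, and the detoxifying enzymes Gstm1 and Sod1 reached 19559 ± 1476 and 13187 ± 1762.

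Several genes that depend on growth hormone in the liver were bright, although the median signal of the growth hormone list was 584 over 10 genes. Igf1, the growth factor that the liver releases under growth hormone (NCBI gene 16000), had a signal of 8919 ± 542 and ranged from 8348 to 9553, at the 98.6th percentile of named genes. Igfals, a subunit of circulating Igf1 complexes (NCBI gene 16005), had 3741 ± 478, and the growth hormone receptor Ghr had 4252 ± 503. The urinary protein probe sets for Mup3 and Mup5, which can read several genes of the family, had 24288 ± 1700 and 18513 ± 1969. Xist, expressed from the inactive X chromosome (NCBI gene 213742), had 1060 ± 440 with a range of 530.9 to 1875. The Y-linked genes Eif2s3y, Kdm5d and Uty had means of 29.6, 8.34 and 33.8, below the floor of 50.04 used here, though Eif2s3y reached 60.1 on replicate 3 and Uty 83.0 on replicate 7. Ddx3y had no probe set with a single gene name and was not analysed here. Of genes with higher expression in females, Cyp2b9 had 7500 ± 505 and Cyp2b13 had 2511 ± 778. The log2 SD of Cyp2b9 was 0.10, and 0.06 without replicate 1. Of genes with higher expression in males, Serpina1e had 28078 ± 2259, Gstp1 6984 ± 958, Cyp7b1 743 ± 92.2 and Cyp4a12b 614 ± 117. The median signal was 2034 for the female-biased list over 9 genes and 536 for the male-biased list over 8.

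**Figure D1:**
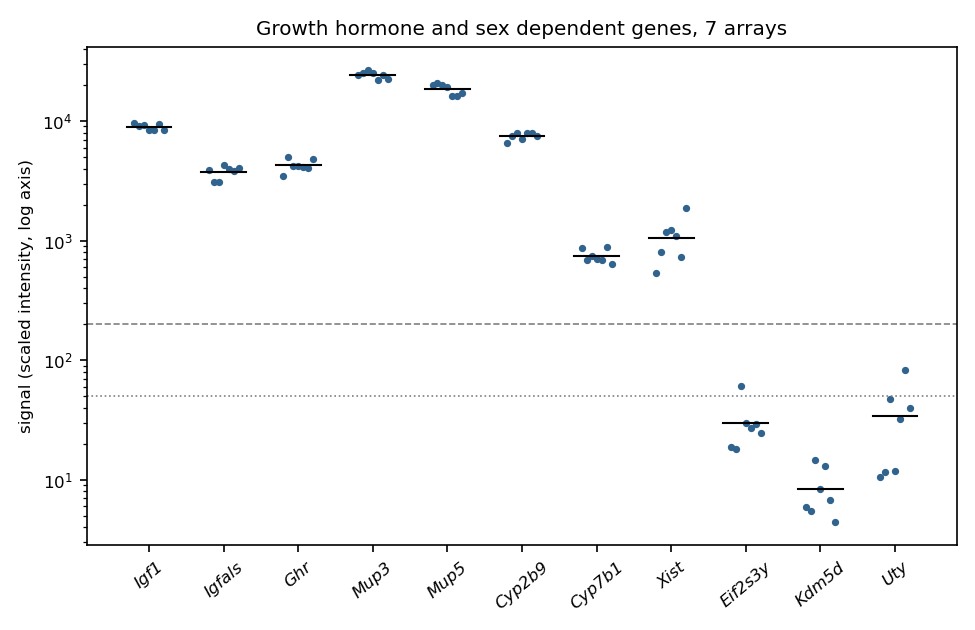
Signal (scaled intensity, log axis) of growth hormone dependent and sex dependent genes, with 1 point per array for 7 arrays, a bar at the mean, a dashed line at the test limit of 200.1 and a dotted line at the floor of 50.04. Igf1 lay between 8348 and 9553 on all 7 arrays, and the Y-linked genes had means under the floor.

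Markers of other cell types had lower signals, with exceptions. The macrophage list had a median of 442 over 18 genes, with the Kupffer cell lectin Clec4f at 1572 ± 198 and the complement gene C1qa at 1484 ± 194. The endothelial list had a median of 266, with Eng at 2291 ± 395. The stellate cell and matrix list had a median of 217, although the proteoglycan Dcn reached 4677 ± 676 and the collagen gene Col1a2 reached 1813 ± 225. Krt8 and Krt18, keratins of hepatocytes and bile duct cells alike, had 2446 ± 339 and 1894 ± 268, while the cholangiocyte list had a median of 73.6. Hemoglobin (Hba-a1) had 9857 ± 1957. The B and plasma cell list had a median of 124 and its highest member, Ighm, had 588 ± 91.5. The T and NK cell list had a median of 42.4, with 8 of 18 genes below the floor on all 7 arrays, and Cd4 at 252 ± 68.5 was its only tested gene. Cell cycle genes had a median of 164, with 5 of 24 below the floor on all arrays.

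The 7 arrays resembled one another. Over tested genes, the Pearson correlation of log2 signals between pairs of arrays ranged from 0.961 to 0.975, a correlation across genes, which are not independent replicates. The share of probe sets below the floor ranged from 27.6% to 29.7%. The 3' to 5' ratio of the Gapdh control lay between 0.788 and 0.907 and that of the beta-actin control between 1.31 and 1.78. The bacterial spike-in controls split the arrays into 2 sets: their mean log2 signal was 10.64 to 10.97 on replicates 1 to 4 and 10.20 to 10.24 on replicates 6 to 8, with a gap of 0.40 between the sets. No 2 arrays held identical values.

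Most genes differed little between animals. The median SD of log2 signals was 0.18 over the 4481 tested genes, 82.7% of genes had an SD under 0.3, and 14 genes had an SD above 1. The steadiest were Myo5b, a motor protein, at 466 ± 9.20, Mrpl58 at 490 ± 11.3, the proteasome gene Psmc5 at 1070.5 ± 26.8, Hsd11b1, which regenerates active glucocorticoid, at 11564 ± 289, and Cmc2 at 793 ± 20.4. Averaging all probe sets of a gene raised the log2 SD of Myo5b from 0.03 to 0.13 and that of Cmc2 from 0.04 to 0.10, while that of Psmc5 was 0.02, against 0.04, as it must be with a second probe set at the floor on all arrays. Without replicate 3, the log2 SD of Cmc2 was 0.01, and without replicate 7 that of Myo5b was 0.02. That of Hsd11b1 was 0.06 with quantile normalization, against 0.04.

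No gene passed the test for more spread between animals than genes of its level. The limma-based test gave 0 of 4481 genes at an adjusted p under 0.05 and 301 genes at an unadjusted p under 0.05, where 224 would arise by chance, and it also gave 0 genes without the robust step (268 unadjusted) or without the trend (245 unadjusted). The smallest adjusted p of the limma-based test was 0.096, for the skeletal muscle actin Acta1 (NCBI gene 11459). Over all 8251 genes, without the filter, 42 genes had an unadjusted p under 0.05, against a nominal 413. A count so far under the nominal one means that the test is poorly calibrated without the filter. Whether the excess of 301 over 224 extends to the unfiltered genes thus cannot be told. Acta1 passed without replicate 4 (adjusted p = 0.029), without replicate 6 (0.036) and with an offset in place of the floor (0.032), and its adjusted p ranged from 0.029 to 0.295 over the alternatives. In simulated data the test recovered 0% of genes whose SD was raised 2 or 3 times and 28.5% of those raised 5 times, so smaller excess spread was not detectable in single genes. Since no gene passed, enrichment among passing genes could not be tested. Genes below were picked as the 25 with the largest SD relative to that expected at their level, a rule chosen after their values were seen.

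**Figure D2:**
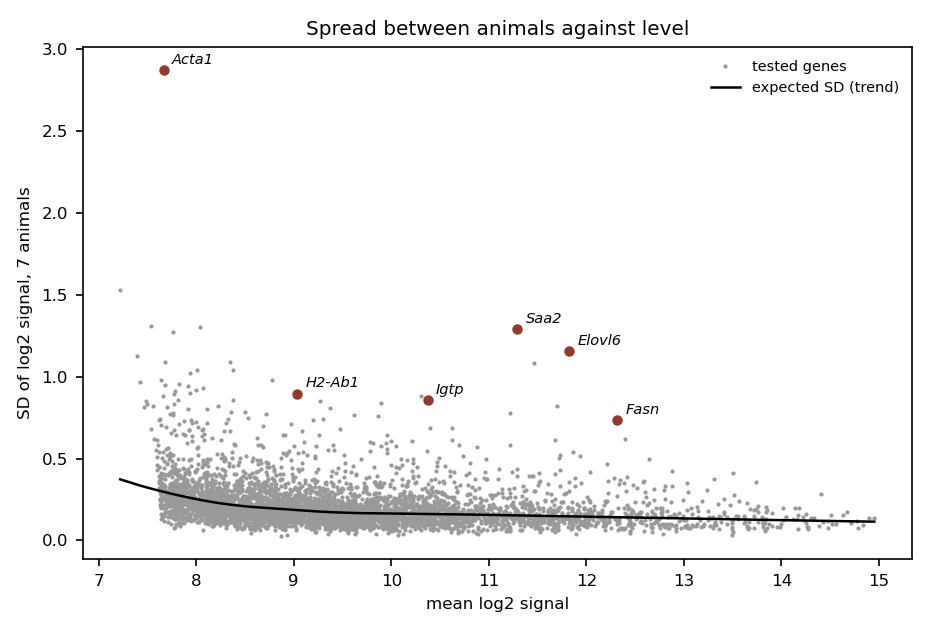
SD of log2 signal over 7 animals against mean log2 signal for 4481 tested genes (grey points), with the expected SD at each level (line) and some of the genes named in the text (red). Acta1 had the largest log2 SD of the named genes, 2.87, and Saa2, Elovl6 and Fasn had SDs of 1.29, 1.15 and 0.73.

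Genes of fatty acid synthesis varied together. Elovl6, which lengthens palmitate (NCBI gene 170439), ranged from 957 on replicate 3 to 8654 on replicate 4, a 9.04-fold range, with the next lowest value at 1482 on replicate 7, and Fasn, the fatty acid synthase, from 2006 on replicate 3 to 8777 on replicate 2. The log2 SD of Fasn was 0.73, and 0.47 without replicate 3. Scd1 was lowest on the same replicate 3, at 16231, and next on replicate 7, at 16497, against 23311 to 25569 on the other 5 arrays. Mid1ip1, an activator of acetyl-CoA carboxylase outside the list, did not share this pattern. It was lowest on replicates 1 and 8, at 339 and 736, and highest on replicate 6, at 1508. Its 2 tested probe sets had r = -0.131 across animals. Its log2 SD was 0.76, but 0.38 with all its probe sets averaged and 0.44 without replicate 1. Without replicate 6 another probe set of Mid1ip1 was the brightest and had 0.26, while the same probe set kept 0.76. Of the 11 tested list genes, 7 had an unadjusted p under 0.05, 5 passed when adjusted over the list alone and 0 when adjusted over all genes tested. Their mean pairwise correlation across animals was 0.555, above all 10000 random lists of the same size and level, whose median was 0.015. The list score ranged from -0.63 on replicate 3 to 0.47 on replicate 4, and had r = 0.790 with the Gapdh 3' to 5' ratio (exact permutation p = 0.032, adjusted p = 0.238).

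Cholesterol synthesis genes also varied together. Lss, which closes the sterol ring, ranged from 288 on replicate 3 to 1255 on replicate 2, and Sqle, the squalene epoxidase, from 692 on replicate 3 to 2809 on replicate 7. Fdps and Idi1, earlier enzymes of the pathway, had 6284 ± 1344 and 2814 ± 846, with Idi1 highest on replicate 7 at 4557. Without replicate 3 the log2 SD was 0.46 for Lss, 0.35 for Sqle and 0.15 for Fdps, against 0.77, 0.61 and 0.36 with it, and that of Idi1 was 0.24 without replicate 7, against 0.40. Of 16 tested genes, 9 had an unadjusted p under 0.05, 7 passed when adjusted over the list alone and 0 over all genes. The mean pairwise correlation was 0.437, above all 10000 random lists.

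Scores of immune genes differed between animals. The interferon response score was highest on replicates 1 and 8, at 0.62 and 0.59. The interferon-induced GTPase Igtp (NCBI gene 16145) had 2826 and 3095 on these and 719 to 1361 on the other 5, and the related Irgm2, named by its spread, had 2561 and 2524 against 690 to 1290. Iigp1, another GTPase of that family, had a mean of 7839 ± 2491, the immunoproteasome gene Psmb9 had 938 ± 406 and Psmb8 had 1259 ± 341. The log2 SD of Psmb9 was 0.54, and 0.36 without replicate 1. Of 15 tested genes, 10 had an unadjusted p under 0.05, 8 passed when adjusted over the list alone and 0 over all genes. The MHC class II score was lowest on replicate 4, at -1.24, where the interferon score was also lowest, at -0.39, and it was highest on replicate 8, at 0.67. H2-Ab1 (NCBI gene 14961) had 158 on replicate 4 and 382 to 1113 on the others, and the invariant chain Cd74, H2-Aa and H2-Eb1 were likewise lowest on that replicate, at 1815, 515 and 445. The log2 SD of H2-Ab1 was 0.90, and 0.51 without replicate 4. All 6 tested MHC class II genes had an unadjusted p under 0.05, and 6 passed when adjusted over the list alone but 0 over all genes. Mean pairwise correlations were 0.651 and 0.937 for the interferon and MHC class II lists, each above all 10000 random lists. Genes so correlated are not independent, so the counts that passed over each list alone are not separate observations. Without the filter on dim genes, the MHC class II list lay at percentile 94.8. The MHC class II score had r = -0.329 with the beta-actin 3' to 5' ratio (exact permutation p = 0.517), but -0.964 with set means removed.

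**Figure D3:**
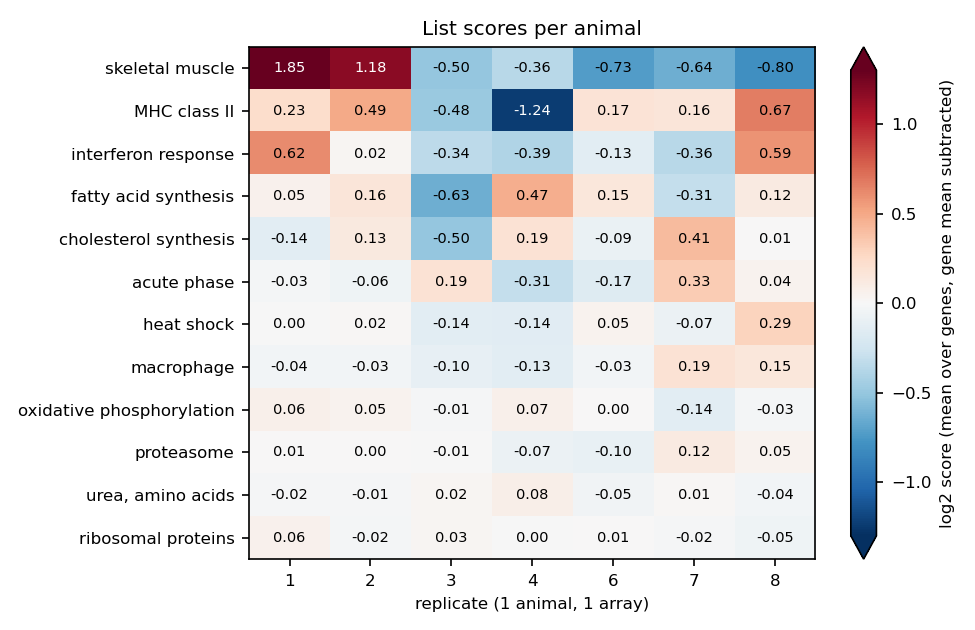
Score of 12 gene lists (rows) in each of 7 animals (columns), as the mean over tested genes of the log2 signal with the gene's mean subtracted (colour scale, clipped at both ends; the number in each cell is the score). The skeletal muscle score reached 1.85 and 1.18 on replicates 1 and 2, the MHC class II score -1.24 on replicate 4, and the ribosomal protein score stayed between -0.05 and 0.06.

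Some skeletal muscle genes were high on replicates 1 and 2. Acta1 had 5991 and 2034 there and 10.5 to 100.4 on the other 5 arrays, 3 of which lay below the floor, so its range was at least 119.7-fold. Atp2a1, the calcium pump of fast muscle, had 1136 and 803 against 122 to 214, and the myosin light chain Myl1 had 848 and 542 against 87.0 to 132. Eno3, the muscle enolase, had 1031 on replicate 1 and 515 on replicate 2, with a log2 SD of 0.75, and 0.40 without replicate 1. Ckm, the muscle creatine kinase, did not: it ranged from 144 to 210 and was lowest on replicate 1. Myh4 was also lowest there, at 103. Pvalb was highest on replicates 2 and 1, at 1726 and 1417, but by far less, with 1075 to 1362 on the other 5. Of 7 tested list genes, 5 had an unadjusted p under 0.05, 5 passed when adjusted over the list alone and 0 over all genes. The mean pairwise correlation of 0.735 was above all 10000 random lists. However, Acta1, Atp2a1 and Myl1 passed the filter on mean signal only through replicates 1 and 2. The counts and the correlation thus follow in part from that selection and are not independent support for the pattern. Both replicates belong to the array set with the higher spike-in signal, and replicate 1 was also high in interferon response genes. Replicates 1 and 2 also had the lowest beta-actin 3' to 5' ratios, 1.34 and 1.31, against 1.56 to 1.78 on the other 5. The muscle score had r = -0.911 with that ratio (exact permutation p = 0.024, adjusted p = 0.253) and rho = -0.536. That r was -0.089 without the 2 arrays farthest from the median ratio and -0.848 with set means removed.

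The acute phase genes Saa2 and Lcn2 were highest on replicate 7. Saa2, a serum amyloid A gene whose probe set can read related genes (NCBI gene 20209), had 12083 there, 6261 on replicate 3 and 1165 to 2237 on the other 5, a 10.4-fold range, and Lcn2 had 714 on replicate 7 against 239.9 to 377. The log2 SD of Lcn2 was 0.54, but 0.24 without replicate 7 and 0.32 with all its probe sets averaged. Its second probe set had an SD of 0.16 and r = 0.536 with the first. The haptoglobin and hemopexin genes Hp and Hpx varied less, with log2 SDs of 0.20 and 0.20. Of 14 tested acute phase genes, 5 had an unadjusted p under 0.05, 1 passed when adjusted over the list alone and 0 over all genes. Their mean pairwise correlation was 0.192, above 98.9% of random lists, but above only 90.1% without replicate 4 and 94.05% with the trend with the Gapdh 3' to 5' ratio removed.

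Several genes with a sex bias or a role in hormone signalling spread widely. Cyp2c39 (NCBI gene 13098) had 7776 and 8879 on replicates 1 and 3 and 1560 to 2252 on the other 5. Cyp17a1, a steroid hydroxylase, had 767 on replicate 3 and 2085 to 3779 on the others, and its log2 SD was 0.33 without replicate 3 and 0.78 with it. Cyp2d9, with higher expression in males, had 992 on replicate 3 against 244 to 546, with a log2 SD of 0.70, and 0.45 without that replicate. Of 8 tested female-biased genes, 6 had an unadjusted p under 0.05 and 6 passed when adjusted over the list alone, but 0 over all genes, and their mean pairwise correlation of -0.02 was near that of random lists, -0.01. Within the growth hormone list, Socs2, a feedback inhibitor of cytokine signalling, ranged from 234 on replicate 2 to 1321 on replicate 7 and the transcription factor Onecut1 from 167 to 525, while Igf1 had a log2 SD of 0.09. The log2 SD of Socs2 was 0.73, and 0.48 without replicate 2. Of the 8 tested genes of the list, 3 had an unadjusted p under 0.05 and 3 passed when adjusted over the list alone, with 0 over all genes.

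**Figure D4:**
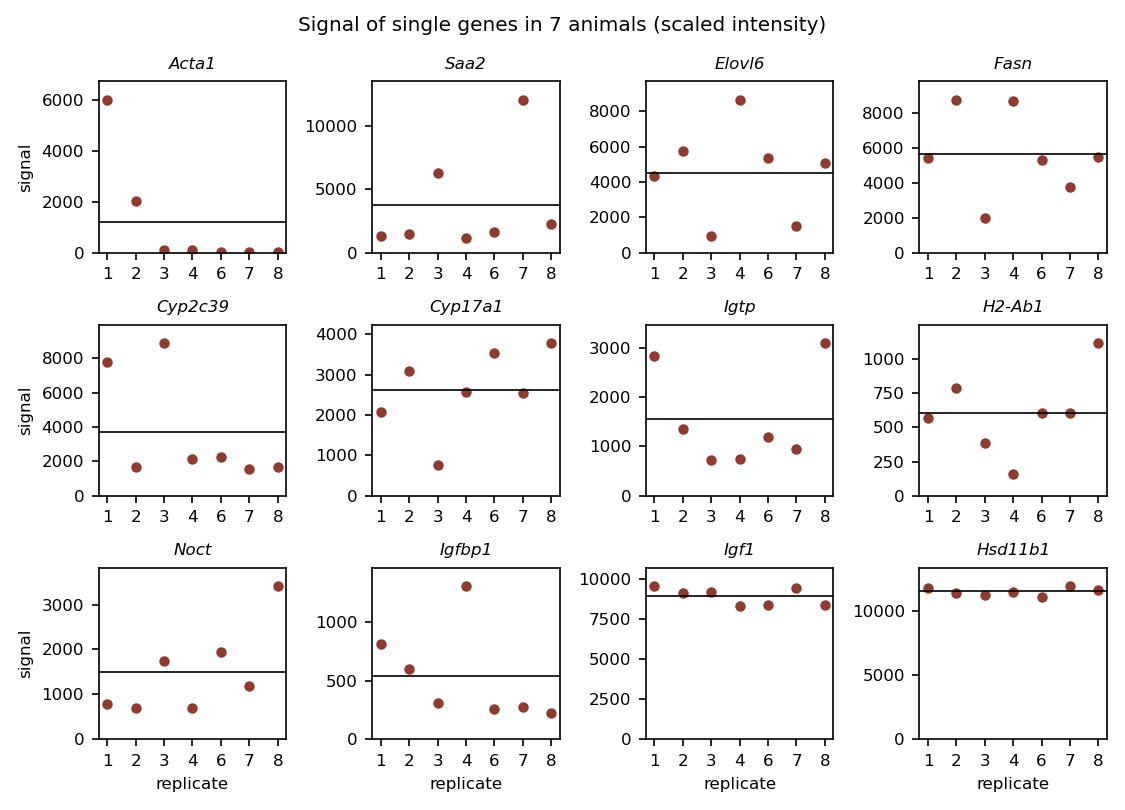
Signal (scaled intensity, axes from 0) of 12 genes in 7 animals, with 1 point per animal and a line at the mean. Acta1 was high on replicates 1 and 2, Saa2 on replicates 3 and 7 and Igtp on replicates 1 and 8, while Igf1 and Hsd11b1 had log2 SDs of 0.09 and 0.04.

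The remaining genes of the 25 with the largest relative spread belonged to no common list. Noct, a gene with a daily rhythm in liver, ranged from 685 to 3409, and Igfbp1, a binding protein induced by fasting, from 223 to 1310. Apob, the structural protein of very low density lipoprotein, had 2996 to 4184 on replicates 1, 6 and 7 and 7046 to 8129 on the other 4. Myl12b was 1859 to 2522 on 4 arrays and 5918 to 6222 on replicates 1, 6 and 7. The others were Hopx, Bcl3, Chrne, Cldn2, Prp2, Lhpp, Cdip1, Snrp1c-ps2 and Gdpd3, with highest over lowest signals between 3.28-fold for Cdip1 and 9.59-fold for Cldn2. For Bcl3, Cldn2, Prp2 and Gdpd3 much of the spread came from a single array: the log2 SD was 0.58 without replicate 7, 0.41 without replicate 4, 0.25 without replicate 8 and 0.24 without replicate 4, against 1.09, 1.04, 0.81 and 1.04 with all arrays and an expected SD of 0.22, 0.22, 0.17 and 0.25. With all probe sets of a gene averaged, the log2 SD was 0.33 for Cdip1 and 0.59 for Noct, against 0.69 and 0.88. That of Chrne, whose other probe sets were too dim to test, was 0.42, against 0.85. That of Igfbp1 was 0.49, against 0.98, as it must be with a second probe set at the floor on all arrays. Across animals the 2 brightest probe sets had r = -0.275 for Cdip1, 0.07 for Noct and -0.624 for Prp2.

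Across the 34 lists with at least 5 tested genes, 16 had a mean pairwise correlation in the top 2.5% of random lists, where 0.85 lists would by chance. Beside those above, these were the secreted plasma protein, fatty acid oxidation, heat shock, endoplasmic reticulum chaperone, immediate early, cell cycle, macrophage, endothelial, oxidative phosphorylation and proteasome lists. Several depended on a single array or on the processing. The heat shock list lay at percentile 71.5 without replicate 8, the endothelial list at 67.2 without replicate 3, and the fatty acid oxidation list at 84.04 without replicate 3. The plasma protein list lay at percentile 66.2 after quantile normalization, a step that by construction evens out the brightest genes. The macrophage list lay at 83.8 and the endoplasmic reticulum chaperone list at 95.5 with the means of the 2 array sets removed. The immediate early list lay at 83.5 without the filter and at 97.1 with the set means removed. It stayed in the top 2.5% in 14 of 19 alternatives, and the acute phase list did in 15 of 19. The cell cycle list stayed in the top 2.5% in 10 of 18 alternatives. The oxidative phosphorylation list lay at 83.9 without replicate 7 and at 70.03 with the trend with the Gapdh 3' to 5' ratio removed, and the proteasome list at 90.7 with that trend removed and 93.5 without replicate 7.

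By the spread of single genes, 14 of the 34 lists had a median log2 SD in the top 2.5% of random lists and 1 had it in the bottom 2.5%. Fatty acid synthesis, cholesterol synthesis, interferon response and muscle genes were each at percentile 100, above the other 10, which included heat shock genes at 99.7, chaperones of the endoplasmic reticulum at 98.8 and, lowest of the 14, immediate early genes at 98.05. For muscle genes this follows in part from the filter, which some of them passed only through replicates 1 and 2. The oxidative phosphorylation list had a median log2 SD of 0.12 over 23 genes, at percentile 1.86 of random lists. In it, Cyc1 had 10728 ± 805 and Atp5a1 9253 ± 500. The log2 SD of Cyc1 was 0.11, but 0.07 without replicate 7 and 0.07 with all its probe sets averaged. The ribosomal protein and proteasome lists, at percentiles 29.1 and 41.96, were near random lists in this respect. The ribosomal protein score had an SD of 0.04 over the 7 animals, with Rplp0 at 8570 ± 461 and Rpl41 at 20720 ± 2031. Among chaperones, Hsp90b1 had 8037 ± 423 and Hspd1 11060 ± 1828. The log2 SD of Hsp90b1 was 0.075, and 0.048 without replicate 7. That of Hspd1 was 0.26, and 0.14 with all its probe sets averaged. Dusp1 and Btg2, immediate early genes, had log2 SDs of 0.44 and 0.71.

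Of 15 list pairs chosen for correlation, 13 had at least 3 tested genes in each list, and 0 passed after adjustment or at an unadjusted p under 0.05. The largest correlation was between MHC class II and macrophage genes, with Pearson r = 0.656 (exact permutation p = 0.081, adjusted p = 0.813, n = 7) and Spearman rho = 0.607 (exact permutation p = 0.167, adjusted p = 0.906). It was 0.193 without replicates 3 and 4, the animals farthest from the median, and 0.515 with array set means removed, and between 0.535 and 0.798 with 1 array left out. Male-biased and female-biased genes had r = -0.554 (exact permutation p = 0.190, adjusted p = 0.813) and rho = -0.321 (exact permutation p = 0.498, adjusted p = 0.906), with r = -0.113 without replicates 3 and 7 and -0.573 with set means removed. With 1 array left out that r lay between -0.842 and -0.436, with the filter at 0.2 it was -0.827 and with all probe sets averaged -0.228. Fatty acid and cholesterol synthesis genes had r = 0.448 (exact permutation p = 0.303, adjusted p = 0.813) and rho = 0.429 (exact permutation p = 0.354, adjusted p = 0.906). That r was 0.782 without replicates 3 and 7, 0.949 without replicate 7 alone, -0.360 without replicate 3 alone and 0.495 with set means removed. Immediate early and heat shock genes had r = 0.491 and rho = 0.607 (exact permutation p = 0.255 and 0.167, adjusted p = 0.813 and 0.906), with 0.474 without replicates 4 and 6, 0.199 with set means removed and between 0.306 and 0.620 with 1 array left out. B cell and macrophage genes had r = -0.443 and rho = -0.07 (exact permutation p = 0.343 and 0.906, adjusted p = 0.813 and 0.906), with -0.486 without replicates 2 and 6, -0.540 with set means removed and between -0.666 and -0.292 with 1 array left out. The other 8 pairs had r between -0.392 and 0.370. The array sets held 4 and 3 arrays, too few for a correlation within each.

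The 2 array sets differed in 0 of 4481 genes by limma at an adjusted p under 0.05, and in 321 at an unadjusted p under 0.05, where 224 would by chance. Of 37 list scores, 3 did not overlap between the sets, where chance gives 5.71% of lists. The plasma protein and xenobiotic P450 scores were higher in the set with higher spike-in signal by 0.18 and 0.23 log2 units (exact permutation p = 0.057, two-sided, adjusted p = 0.529 for each), and the third was the skeletal muscle score. The macrophage score, whose values overlapped, was lower in that set by 0.18 log2 units, with the same exact permutation p. No score had a smaller p than 0.057 in the exact permutation test. The 35 splits allow no p under 0.029, so a single list could not pass after adjustment over 37 lists. The adjusted p thus leaves a difference between the sets open. No list score followed the Gapdh or the beta-actin 3' to 5' ratio after adjustment over 37 lists, while 6 did for Gapdh and 4 for beta-actin at an unadjusted p under 0.05. The closest was the conjugation and antioxidant list, with r = 0.965 (exact permutation p = 0.0014, adjusted p = 0.051, n = 7) and rho = 0.929 (exact permutation p = 0.0067, adjusted p = 0.220). That r was 0.942 without the 2 arrays farthest from the median ratio and 0.962 with set means removed. The oxidative phosphorylation score had r = 0.879 (exact permutation p = 0.0030, adjusted p = 0.055), with 0.865 without those 2 arrays and 0.900 with set means removed. The acute phase score had r = -0.880 with the Gapdh ratio (exact permutation p = 0.010, adjusted p = 0.127) and rho = -0.786 (exact permutation p = 0.048, adjusted p = 0.350), with r = -0.563 without those 2 arrays and -0.872 with set means removed. The endoplasmic reticulum chaperone score had r = -0.848 (exact permutation p = 0.022, adjusted p = 0.20) and rho = -0.857 (exact permutation p = 0.024, adjusted p = 0.220), with r = -0.954 without those arrays and -0.815 with set means removed. The fatty acid synthesis score had r = 0.790 (exact permutation p = 0.032, adjusted p = 0.238) and rho = 0.571 (exact permutation p = 0.20, adjusted p = 0.617), with r = 0.296 without those arrays and 0.856 with set means removed. The sixth was the exocrine pancreas score. The 4 for beta-actin were the growth hormone, gluconeogenesis, neutrophil and skeletal muscle scores, with r = 0.751, -0.829, 0.861 and -0.911.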

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

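All tests in this part except the choice of the outlier criterion were chosen after the results were seen. Of 168 values checked over the 7 arrays, 15 had 1 array apart from the others by Dixon's criterion, where chance gives about 1 in 20, or 8.40. That rate does not hold strictly here, since some of the genes were picked for their large or small spread.

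Replicate 3 stood apart in 6 of them. Pzp was highest there at 26867 (others 20979 to 23446), Cmc2 at 838 (777 to 793), Cyp2d9 at 992 (244 to 546) and the clock-controlled gene Dbp at 1492 (755 to 1029). Eif2s3y was highest there at 60.1 (18.1 to 29.8), near the floor. Fdps was lowest there at 3652 (6080 to 7819).

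Replicate 4 was lowest for the score of clock genes driven by E-box elements, at -0.35 (others -0.01 to 0.14), with Per1 at 155 (337 to 428), and for Gdpd3 at 52.0 (259 to 403). Replicate 7 was highest for Idi1 at 4557 (1835 to 2861) and Lcn2 at 714 (239.9 to 377). Replicate 2 had the lowest growth hormone list score, -0.45 (others -0.04 to 0.24). Replicate 8 had the lowest Prp2 signal, 196 (666 to 986), but the 2 brightest probe sets of Prp2 had r = -0.624 across animals.

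Replicate 1 was highest for Acta1 at 5991 (others 10.5 to 2034) and for Eno3 at 1031 (others 238 to 515). Both belong to the pattern of muscle transcripts on replicates 1 and 2. The split of arrays seen in the spike-in controls was weighed. Replicates 3 and 4, in the same set as replicates 1 and 2, had muscle scores of -0.50 and -0.36, against 1.85 and 1.18. This contrast within the set argues against the set as the whole cause. With the set means removed, the mean pairwise correlation of the 7 tested list genes stayed above 100% of random lists. That step cannot remove a contrast within a set, so its result adds nothing. Striated muscle carried into the sample is a candidate explanation: in a second list of 34 muscle genes, 10 of the 22 above the floor (45.5%) had replicates 1 and 2 highest, against 4.51% of 7184 other genes. That share missed the 50% set for this explanation, but it exceeded that of other genes, so the explanation stays open. In the first list, 9 of 12 genes had replicates 1 and 2 highest. Ckm and Myh4, abundant in muscle, were lowest on replicate 1, at 144 and 103. Both values lie under the test limit of 200.1, and no detection calls were used. Ckm and Myh4 were also chosen after their values were seen, so they decide nothing about this explanation. The second list was corrected once after its result was seen, to take out 2 genes whose values had been seen earlier, and the share with them also lay under 50%. The muscle score also had r = -0.911 with the beta-actin 3' to 5' ratio (exact permutation p = 0.024, adjusted p = 0.253). With the trend with that ratio removed, the mean pairwise correlation was above 99.5% of random lists. RNA integrity as a part of the pattern thus stays open. Some of the 7 tested genes passed the filter on mean signal only through replicates 1 and 2. No biological explanation was tested.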

How the results depend on the processing

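The alternatives with array sets, without replicates 1 and 2 together, and at an unadjusted p were chosen after seeing the data, as was the count of lists that vary together. The number of genes with more spread than genes of the same level was 0 in all fits except 1 gene, Acta1, with an offset in place of the floor, and 0 to 1 with 1 array left out. The cause was not tested. Enriched lists could not be tested under the alternatives fixed beforehand, where 0 or 1 genes passed, and numbered 11 when genes at an unadjusted p under 0.05 were used. The count of 11 treats genes as independent, although genes of a list can vary together on the same arrays. Correlated pairs numbered 0 throughout. The number of lists that vary together, 16, ranged from 13 to 16 with 1 array left out and from 12 to 17 otherwise. The correlation of fatty acid with cholesterol synthesis genes turned to -0.360 without replicate 3, and ranged from -0.360 to 0.949 with 1 array left out. The other 8 pairs gave the opposite sign in 24 of 151 values under alternatives, 7 of them at least once. The filter at 0.8 left too few genes for the B cell pairs and for the cell cycle, endothelial and muscle lists. The mean signals of Igf1, Igfals, Mup3 and Mup5 moved by less than their SDs without scaling, with quantile normalization and with each array left out. Of 121 genes checked, the log2 SD moved by more than 1.5 times for 32 with at least 1 array left out, 1 with median centring, 17 with quantile normalization and 23 with all probe sets averaged, 7 of them with a probe set at the floor on all arrays, which shrinks an SD by construction. No paired analysis was possible because there is 1 group. Signals near the floor limit what can be said of dim genes.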

Other observations

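The test of the dwarf label was planned before the data were examined, and all other tests in this part were chosen after the results were seen.

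Several genes known from other tissues had signals well above the floor on all 7 arrays. Lep, the adipocyte hormone leptin, had 1466 ± 305 (SD, n = 7), Pvalb 1363 ± 193, the pancreatic elastase gene Cela1 1277 ± 128 and the neutrophil receptor gene Csf3r 981 ± 120. Pvalb and Acta1 were both highest on replicates 1 and 2, with 1417 and 1726 for Pvalb and 5991 and 2034 for Acta1. On replicate 8, where Acta1 had 42.9, Pvalb still had 1314. In the lists these genes stand for, most other members were dim, with median signals of 116 for adipocyte, 187 for exocrine pancreas and 53.9 for neutrophil genes. Tk1 had 1488 ± 171 while the cell cycle list had a median of 164, and its log2 SD was 0.16, but 0.61 with all its probe sets averaged, the other being too dim to test, and 0.10 without replicate 7. No cause was tested.

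Different probe sets of 1 gene often disagreed on which animals were high. Over 588 genes with at least 2 tested probe sets, the median correlation of the 2 brightest across animals was 0.197, against -0.0014 for random gene pairs, and 8.16% exceeded 0.8, against 1.56% of random pairs. For the 60 genes with an SD of at least 2 times that expected, the median was 0.456, and for the other 528 it was 0.173.

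The description field names dwarf animals, which lack growth hormone and would have little hepatic Igf1. Igf1 exceeded the test limit of 200.1 on 7 of 7 arrays, with a lowest value of 8348, which argues against the livers having come from growth hormone deficient dwarf animals. The value that decides this was set before the data were examined. Other errors in the labels were not tested.

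Fatty acid synthesis, interferon response and MHC class II genes each varied together between animals, and technical explanations were weighed. With the means of the 2 array sets removed, their mean pairwise correlations stayed above 100%, 100% and 100% of random lists. With the trend with either 3' to 5' control ratio removed, the lower percentile was 99.9, 100 and 100. Fatty acid synthesis and interferon response scores differed between the sets by only 0.03 and -0.05 log2 units, so removing set means could change little. These small differences themselves argue against the set as the whole source for those lists. For MHC class II, which differed by -0.58, the percentile with set means removed does so. Removing a linear trend argues only against a straight-line effect of either ratio as the whole source. Both steps were applied separately. The fatty acid synthesis score had r = 0.790 with the Gapdh ratio (exact permutation p = 0.032, adjusted p = 0.238), and 0.856 with set means removed. With the beta-actin ratio, the MHC class II score had r = -0.329 (exact permutation p = 0.517), but -0.964 with set means removed. The interferon response score had r = -0.466 with it, and -0.671 with set means removed. RNA integrity as a part of the variation of all these lists thus stays open. Hypotheses that stay open and were not tested include differences in recent feeding, infection or cell makeup between animals, and dissection or sampling time.

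The limma comparison of the 2 array sets gave 0 genes, so all 35 of the 35 splits of 7 arrays into 4 and 3 gave as many, with 2 genes in the highest other split, and the count decides nothing about chance. At an unadjusted p, 2 of the 35 splits, the real one included, gave at least 321 genes, and the highest other gave 376. The plasma protein score difference between sets was 0.18 log2 units, and 40.1% of it was left after quantile normalization, a step that by construction evens out the brightest genes.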
